A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

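RNA of wild-type and sub1Δ yeast was labelled with Cy3 or Cy5 and hybridised to spotted open reading frame arrays, 4 arrays of untreated cells and 4 of cells exposed to 4NQO. Per the series' design text and the labels, the arrays were scanned with a GenePix instrument, and the authors subtracted the background and applied LOWESS normalisation with a smooth parameter of 0.33. They deposited the log2 ratio of Cy3 over Cy5 for each spot. The submitters' processing notes name limma 2.12.0, and the design text describes a moderated test on 4 technical arrays from 2 independent experiments. Whether dye-swapped arrays were turned before deposit, and why some spots have no value, is not given in the sources used here. The deposited array medians were 0.13, -0.21, -0.01 and -0.08 untreated and 0.14, -0.49, 0.54 and -0.66 with 4NQO, so the values are not centred on 0, and neither intensities nor background levels were used here.

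Arrays with the mutant in Cy5 were multiplied by -1, so that every ratio is sub1Δ over wild type. As deposited, dye-swapped and unswapped arrays of an experiment correlated negatively in 3 experiments (r = -0.21, -0.26 and -0.33), as unturned swaps do, while untreated experiment 2 gave a Pearson r of 0.19 and a Spearman rho of -0.0488, near 0 and of opposite sign. By rank all 4 pairs were negative. The rule set in advance was to turn the swaps of a condition if they correlated negatively and to leave them if positively. By rank it turns all swaps, by Pearson r it gives no single answer for untreated cells, and because the dye labels and the stated ratio apply to all arrays, all were treated alike. The alternatives that all swaps, or that 1 alone, were already turned were added after the data were seen. The turned medians of the dye-swap means were -0.16 and -0.01 untreated and -0.37 and -0.72 with 4NQO.

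Of 6216 spots, 3344 had 1 gene symbol in the platform annotation, 387 several and 2485 none. Symbols were updated through gene identifiers with the RefSeq gene table of assembly R64, which matched 3343 of the 3344, and only single-symbol spots were named. No genome build is given for the array, so no coordinates are printed. Spots of 1 gene were averaged (207 genes had 2 or more), giving 5999 features, of which 3127 were genes and 1654 had a value on all 8 arrays. Duplicate spots of a gene correlated across genes with r = 0.28 and 0.32 in the untreated dye-swap means and 0.44 and 0.27 with 4NQO.

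The 2 arrays of a dye swap hold the same RNA samples and were averaged to 1 value where both had one, so a condition has n = 2 experiments. A single limma fit (version 3.58.1, R 4.3.3) on the 4 dye-swap means estimated 1 strain ratio per condition and their difference, with a spread shared by both conditions and moderated by empirical Bayes (prior degrees of freedom 16.8). A feature was tested where both dye-swap means of the condition existed. Without both means in the other condition, its own spread came from the tested condition alone. All tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method, the threshold was 0.05 and no minimum fold was set. That experiments were separate cultures is stated only as independent experiments.

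A set of 40 gene lists covering DNA repair, stress, ribosome, metabolism, cell cycle, mating type and other processes was fixed before the data were examined, and lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01. Because camera does not accept missing values, its pre-ranked form was applied to the moderated statistics, a departure from the planned call. Camera with an estimated correlation and fry were run on the 1654 complete features. A call lost there can come from the features, the residual degrees of freedom (2) or the correlation, which were not separated. For the oxidative stress list the estimate (0.0058) lay below the preset value, so there the correlation is not the cause. On those features the preset correlation called 4 of the 5 lists with 4NQO. Fry tests a list against 0 and camera against the other features.

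Genes to be named were also fixed by rule: the 10 largest rises and 10 largest falls past the threshold with the same sign on all 4 arrays, 5 and 5 for the difference, and, where fewer than 5 passed, the genes of smallest p up to 5, said not to pass. Up to 4 members of each list described (those with the smallest p), SUB1, and a few genes of 4NQO resistance and strain markers were added. SUB1, IMD2, RNR3, HUG1, RAD2 and most marker genes had no single-named spot and are not analysed here.

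The procedure was run on 100 simulated data sets with the real pattern of missing values, the fitted spread, and 200 features changed in the 4NQO comparison, 50 at each size. It recovered on average 6.12% of changes of 1, 51.8% of changes of 2 (18% to 76%), 93.2% of changes of 3 and 99.7% of changes of 4 on the log2 scale, and 5.55% of its calls were unchanged features. In 26 of the 100 simulations at least 1 feature was called in untreated cells, where nothing had been changed, with 6 as the highest count. The simulation gave a feature the same spread in both conditions and shifted no dye-swap median. Real dye-swap means spread more across features with 4NQO (SD 1.35 and 1.49) than untreated (1.05 and 0.73). The simulated counts and the 5.55% therefore do not carry over to the real calls in either condition. The prior degrees of freedom, simulated at 16.8, were estimated at 4.94 in the lowest case and as infinite in 29 simulations, so this part of the test is poorly determined with 4 dye-swap means. A list of 35 features shifted by 1 was called in all 100 simulations, and 6 of 10000 random lists were called, but simulated features were independent and real genes are not. An earlier version of this check used 1 simulation and was replaced when a second draw gave other counts.

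Other analyses chosen before the data were seen took arrays as independent replicates, the experiment as a random block, a dye term, array medians centred, arrays scaled to a common median absolute value, features on all 8 arrays only, dye-swap means from 1 array where the other had no value, robust empirical Bayes, each condition fitted alone, the experiment number as a block, a minimum absolute log2 of 1, an adjusted p under 0.10, and each experiment left out. Added after the data were seen were centring of each of the 48 spot blocks (blocks held 5.77% to 15.0% of the variance of an array), every spot as its own feature, leaving out the sparsest array, and the direction of the swaps. Paired use of the experiment numbers was not made in the main result because no label states that a number marks a shared culture.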

Results

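Gene expression was compared between wild-type budding yeast (Saccharomyces cerevisiae, strain YPH500) and a strain lacking SUB1, the gene of a conserved transcription coactivator related to human PC4. The 2 strains were grown in rich medium and sampled before treatment and 1 h after addition of 4-nitroquinoline 1-oxide (4NQO), a mutagen that forms bulky DNA adducts and oxidative damage. The labels give the dose as 1 µg/µl. Each of the 8 arrays carried RNA of both strains, 1 strain per dye, so every value is a ratio of sub1Δ to wild type within 1 array. Each condition was covered by 2 independent experiments, and each experiment was hybridised a second time with the dyes exchanged, giving 4 arrays per condition and 2 replicates per condition. No array compared treated with untreated cells, so the response of a single strain to 4NQO was not measured. No untreated sample was taken at 1 h. An effect of 4NQO thus cannot be told apart from one of the added hour in culture.

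The arrays held 6216 spots of amplified open reading frames. Between 266 and 1659 spots lacked a value on 7 of the arrays, and 3234 on the dye-swapped array of 4NQO experiment 2. The number of arrays limits the precision: dye-swap means of the 2 experiments correlated across features with r = 0.14 in untreated cells and r = 0.51 with 4NQO (features are not independent replicates). Untreated experiment 1 correlated with 4NQO experiments 1 and 2 at r = 0.50 and 0.37, and untreated experiment 2 at 0.18 and 0.12. Agreement across features was thus not confined to the 4NQO experiments. The p-values of single genes rest on the spread between the 2 experiments of a condition. It was pooled over both conditions only for the 1654 features with all 4 dye-swap means. For other features it came from the tested condition alone, before moderation. The p-values of gene lists rest also on the variation among genes. SUB1 had no spot with a single gene name, so the deletion could not be read from the arrays and the direction of the ratios rests on the dye labels and the stated Cy3 over Cy5 ratio.

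The first comparison asked which transcripts differed between the strains before treatment. No named gene passed the test in untreated cells. The genes with the smallest p that were higher in sub1Δ on all 4 arrays were ANB1, a hypoxic translation factor gene, at a log2 ratio of 2.03 ± 1.59 (SD, n = 2 experiments; adjusted p = 0.33), GRE1, a stress-induced gene, at 1.62 ± 0.81, BGL2, a cell wall glucanase gene, at 1.71 ± 1.97, and the chaperone genes SSC1 at 1.47 ± 0.41 and SSA2 at 1.64 ± 1.21. The lowest ratios by the same rule were those of YHR022C at -2.35 ± 0.09 (adjusted p = 0.22), YGL260W at -2.30 ± 0.17, BLI1, a gene of an endosomal complex, at -2.15 ± 0.86, HSP12, a membrane stress protein gene, at -2.10 ± 0.58, and SLM3, a mitochondrial tRNA modification gene, at -1.99 ± 0.30. None of these 10 genes passed. With untreated cells fitted alone, YHR022C (adjusted p = 0.015), YGL260W (0.019), BLI1 (0.032), HSP12 (0.035), SLM3 (0.049) and ANB1 (0.049) did.

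Of 3457 features tested with limma's moderated test in untreated cells, 1 had a Benjamini-Hochberg adjusted p under 0.05, and 198 had an unadjusted p under 0.05 where 172.85 would be expected with no difference. The called feature was the spot 46.1.2 (probe 46.1.2), without a gene name here and singled out after its value was seen, at -4.72 ± 2.52 (SD, n = 2; adjusted p = 0.011), with experiments at -6.50 and -2.94 and not the same sign on all 4 arrays. The dye-swapped array of untreated experiment 2 correlated with its partner at a Pearson r of -0.19 and a Spearman rho of 0.0488 after turning, against 0.21 and 0.26 in untreated experiment 1. With untreated cells fitted alone, without the 4NQO experiments that share in the estimate of the spread, the test called 42 features. Leaving out either 4NQO experiment amounts to that fit.

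None of the 36 gene lists with at least 5 tested members was shifted in untreated cells (camera, smallest adjusted p = 0.071). That value belonged to amino acid biosynthesis and Gcn4 targets, with a median log2 ratio of 0.56 over 21 genes, and to nitrogen catabolite genes, with -0.70 over 6 genes. With array medians centred both lists passed narrowly (camera adjusted p = 0.047 and 0.049). Ribosomal protein genes had a median of -0.08 over 47 genes, 20 of them above 0, and glycolysis and gluconeogenesis genes a median of 0.43 over 14 genes. DNA damage-induced genes had a median of 0.58 over 6 genes (adjusted p = 0.45) and nucleotide excision repair genes -0.49 over 5 genes (adjusted p = 0.62). No member of these 6 lists passed the test. When adjusted over the list alone, 1 nitrogen catabolite gene passed as lower and none passed in the other 5 lists.

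The second comparison asked which transcripts differed between the strains after 4NQO. Ribosomal protein genes were higher in sub1Δ: of 35 tested, 23 were called higher, 1 lower and 11 did not pass, with a median log2 ratio of 1.84. Proteasome, glycolysis, ergosterol and oxidative stress genes were also shifted upward, while the median of all tested features was -0.56. All 5 list calls are lost when camera estimates the correlation between genes (adjusted p = 0.57), a form run on complete features only and with the 2 residual degrees of freedom of the fit. They are absent too with fry (0.13 to 0.25), which asks instead whether a list differs from 0. Estimated correlations were 0.0058 for oxidative stress and 0.096 (ribosomal proteins) to 0.45 (glycolysis) for the other called lists, against the preset 0.01. The largest rise among named genes with the same sign on all arrays was that of URA5, which encodes an enzyme of pyrimidine synthesis, at 14.2-fold (log2 3.83 ± 0.72, SD, n = 2; adjusted p = 0.0032). The largest fall by the same rule was that of BLI1, at a log2 ratio of -3.56 ± 0.10 (adjusted p = 0.0032).

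**Figure D1:**
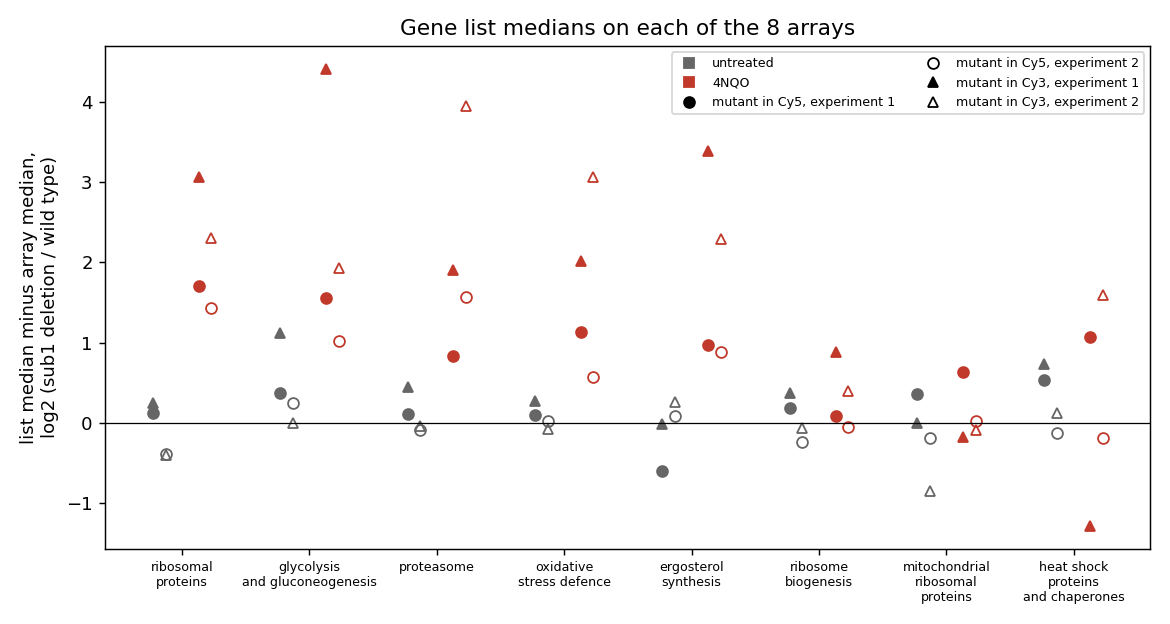
Median log2 ratio (sub1Δ over wild type) of 8 gene lists on each array, minus that array's median over all features; grey untreated, red 4NQO, circles mutant in Cy5, triangles mutant in Cy3, filled experiment 1, open experiment 2. Ribosomal protein medians lie between 1.44 and 3.06 on the 4NQO arrays and between -0.40 and 0.25 on the untreated arrays.

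Among the 10 named genes with the largest rise, 3 encode ribosomal proteins: RPL10 at a log2 ratio of 3.57 ± 3.28 (SD, n = 2), RPL28 at 3.39 ± 2.04 and RPS25B at 8.03-fold. CYB5, which encodes cytochrome b5, was at 3.35 ± 0.96, BGL2 at 3.32 ± 0.60, GPT2, a glycerolipid acyltransferase gene, at 3.15 ± 0.49, and PRE5, a proteasome core subunit gene, at 3.07 ± 1.96. YLR257W at 3.14 ± 2.76 and YPL216W at 3.12 ± 0.63 complete the group. The genes with the largest fall after BLI1 were HES1, a sterol-binding protein gene, at -3.28 ± 3.04, CKS1, which encodes a cofactor of the cell cycle kinase, at -3.15 ± 1.05, and DAM1, a kinetochore gene, at -3.12 ± 1.74. They were followed by SRO77 at -2.87 ± 2.04, ILS1, an aminoacyl-tRNA synthetase gene, at -2.87 ± 3.30, YOL163W at -2.86 ± 1.76, GIP1, a sporulation gene, at -2.79 ± 1.20, PEP1, a vacuolar sorting receptor gene, at -2.79 ± 0.96, and QDR3, a multidrug transporter gene, at -2.78 ± 1.60. All 20 genes had the same sign on all 4 arrays, with limma adjusted p between 0.0032 and 0.021. The values of HES1 and ILS1 rest mainly on 1 array each, at -10.7 and -10.2, with the other 3 arrays between -1.22 and -0.18. With array medians centred, the 10 genes with the largest rise kept their calls, as did BLI1, CKS1, DAM1 and PEP1, while HES1, SRO77, ILS1, YOL163W, GIP1 and QDR3 no longer passed (adjusted p between 0.076 and 0.13).

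**Figure D2:**
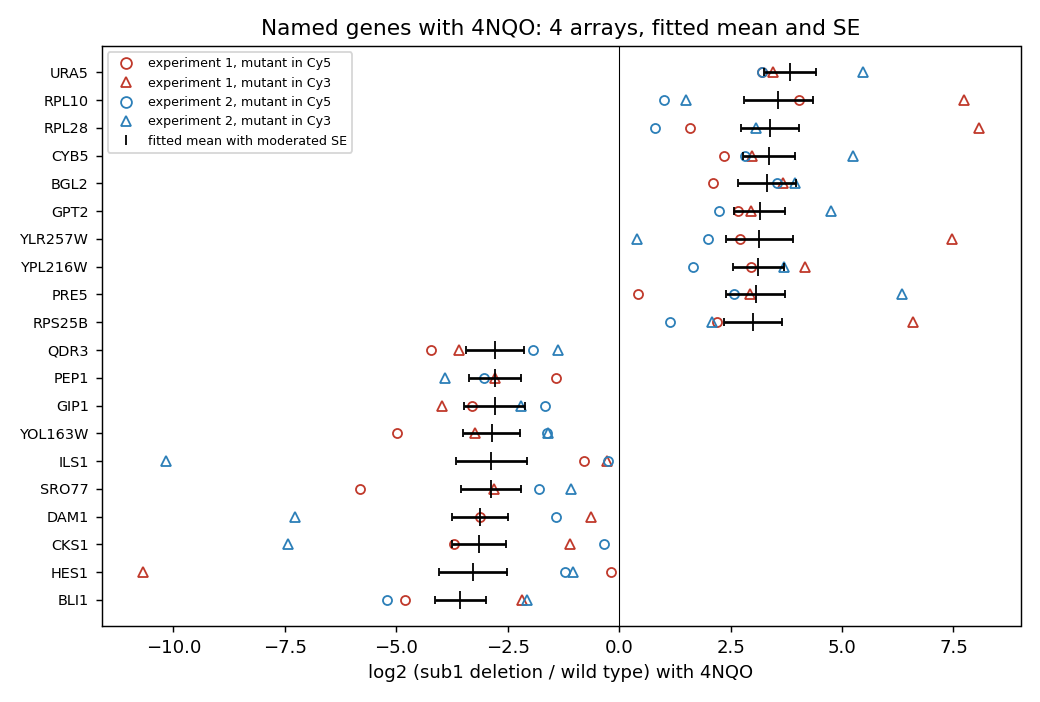
Log2 ratio (sub1Δ over wild type) of the 20 named genes with 4NQO on each of the 4 arrays (red experiment 1, blue experiment 2, circles mutant in Cy5, triangles mutant in Cy3), with the fitted mean and its moderated SE as a black bar. All points of a gene lie on 1 side of 0, and ILS1 and HES1 each have 1 array beyond -10.

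Ribosomal protein genes gave the clearest list result (camera adjusted p = 8.3e-15; adjusted p = 0.57 with an estimated correlation). Adjusted over the list alone, 27 were higher and 2 lower. RPS22A was at a log2 ratio of 2.98 ± 1.85 (SD, n = 2), and RPL7B was the member called lower, at -1.76 ± 0.61. Several ribosomal protein genes have near-identical copies that can bind the same spotted sequence, so single members are uncertain. After centring of array medians the count was 23 higher and 0 lower, and the median rose to 2.30.

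Proteasome genes had a median log2 ratio of 1.72 over 13 tested genes, of which 7 were called higher, 1 lower and 5 did not pass (camera adjusted p = 2.4e-05; adjusted p = 0.57 with an estimated correlation). Adjusted over the list alone, 10 were higher and 1 lower. Besides PRE5, the members with the smallest p were SCL1, a core subunit gene, at 2.37 ± 0.27 (SD, n = 2), and the regulatory particle genes RPN6 at 2.46 ± 1.37 and RPN5 at 2.20 ± 0.15. UMP1, which encodes a proteasome assembly factor, was the member called lower, at -1.81 ± 0.06, and it lost the call after centring (adjusted p = 0.20).

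Glycolysis and gluconeogenesis genes had a median log2 ratio of 1.95 over 11 tested genes, 5 called higher, none lower and 6 not passing, with 8 higher when adjusted over the list alone (camera adjusted p = 1.3e-04; adjusted p = 0.57 with an estimated correlation). The glyceraldehyde-phosphate dehydrogenase genes TDH1, TDH2 and TDH3 were at 2.64 ± 1.28, 2.28 ± 1.79 and 1.95 ± 1.46 (SD, n = 2), but their sequences are so alike that the spots may not tell them apart. ADH1, the main fermentative alcohol dehydrogenase gene, was at 1.97 ± 1.79. The 3 TDH genes stood far higher on the dye-swapped array of experiment 1, at 5.35 to 5.47, than on the other 3 arrays, at 0.48 to 1.96.

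Ergosterol synthesis genes had a median log2 ratio of 1.51 over 8 tested genes, with 4 called higher, 1 lower and 3 not passing, in total and when adjusted over the list alone (camera adjusted p = 0.044; adjusted p = 0.57 with an estimated correlation). ERG25, ERG28 and ERG3, genes of late steps of sterol synthesis, were at 2.87 ± 0.54, 2.56 ± 0.37 and 2.06 ± 0.70 (SD, n = 2). The member called lower was HES1. Oxidative stress defence genes had a median of 1.62 over 6 tested genes, with 3 called higher, 0 lower and 3 not passing, and 4 higher when adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.57 with an estimated correlation). These were AHP1 and TRX2, of the peroxiredoxin and thioredoxin systems, at 2.51 ± 3.04 and 1.84 ± 0.67, and MXR1, a methionine sulfoxide reductase gene, at 1.78 ± 0.11. AHP1 lost its call with array medians centred (adjusted p = 0.060) and MXR1 with spot blocks centred (0.19). The superoxide dismutase gene SOD1, at 1.47 ± 1.30, did not pass over all genes (adjusted p = 0.086). The ergosterol and oxidative stress lists both lost their calls when each spot block was centred (camera adjusted p = 0.070), keeping 86.7% and 71.4% of their shift, and the oxidative stress list also without 4NQO experiment 1 (adjusted p = 0.12) or without 4NQO experiment 2 (adjusted p = 0.39). The list ergosterol synthesis, 4NQO, lost its call without 4NQO experiment 1 (adjusted p = 0.068), and narrowly without either untreated experiment (adjusted p = 0.0533).

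The other 22 lists with at least 5 tested members were not called. Amino acid biosynthesis and Gcn4 targets had a median log2 ratio of 0.67 over 10 genes (camera adjusted p = 0.061) and purine and pyrimidine synthesis 0.68 over 8 genes (adjusted p = 0.070). Ribosome biogenesis genes, which often move with ribosomal protein genes in yeast stress responses, had a median of -0.26 over 19 genes (adjusted p = 0.70), with 1 called higher and 1 lower. Mitochondrial ribosomal protein genes were at -0.24 over 20 genes, 3 of them called lower, and TCA cycle and respiration genes at 0.09 over 16 genes, with 1 called in each direction. Heat shock proteins and chaperones had a median of -0.58 over 9 genes and general stress genes -0.07 over 8 genes. RNA polymerase III machinery, relevant because Sub1 also occupies genes transcribed by that enzyme, was at -0.77 over 6 genes with 1 called lower (adjusted p = 0.50). Meiosis and sporulation genes had a median of -1.70 over 6 genes, with 3 called lower, and drug efflux genes -1.89 over 5 genes, with QDR3 and AQR1 called lower (adjusted p = 0.19 for both lists). Trehalose and glycogen metabolism, with 4 tested genes too small for the list test, had a median of -1.80, with 2 called lower, 3 when adjusted over the list alone. In these 22 lists no call in the lower direction remained after centring of array medians.

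DNA repair lists were too sparsely measured with 4NQO for the list test. Of the DNA damage-induced genes, 3 were tested and 2 were called higher: RNR2 at a log2 ratio of 2.46 ± 0.09 (SD, n = 2) and RNR4 at 2.71 ± 0.23, which encode the 2 proteins of the small subunit of ribonucleotide reductase and were named after their values were seen. No nucleotide excision repair gene of 2 tested and no recombination repair gene of 4 tested passed. Of the genes chosen in advance, GPD1 (0.16 ± 2.02), ADE2 (-0.25, experiments 0.81 and -1.32) and LYS2 (-1.48 ± 1.06, adjusted p = 0.082) were measured with 4NQO and did not pass. LYS2 passed narrowly without 4NQO experiment 2 (-2.23, adjusted p = 0.0498) and was at -0.73 without experiment 1. In untreated cells GPD1 (-0.52 ± 0.64), ADE2 (0.74 ± 1.77) and LYS2 (-0.75 ± 0.88) did not pass, and their experiments lay at -0.97 and -0.06, -0.51 and 1.99, and -1.37 and -0.13. The 4NQO exporter gene SNQ2 lacked the values needed for a test.

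In total 428 of 2194 features (19.5%) passed with 4NQO in limma's moderated test, 199 higher and 229 lower in sub1Δ. Of these, 219 had a single gene name, 107 higher and 112 lower, and 339 had the same sign on all 4 arrays. An unadjusted p under 0.05 was reached by 822 features, against 109.7 expected with no difference. With array medians centred 212 features passed, 195 higher and 17 lower (92.0% higher, against 46.5% as deposited), and, with each spot block centred, 408, of which 284 were higher and 124 lower (69.6% higher). The share of lower genes thus depends on the centring. No feature passed when arrays were scaled to a common spread, when only features on all 8 arrays were used (smallest adjusted p = 0.057), when 1 array of a dye swap was allowed to stand alone, without the sparsest array, or when the dye-swapped arrays were taken as already turned. The ribosomal protein, proteasome, glycolysis and ergosterol lists stayed higher under the first 4 of these choices, and the oxidative stress list under the first alone. With 4NQO cells fitted alone, 94 passed, and leaving out either untreated experiment amounts to that fit.

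**Figure D3:**
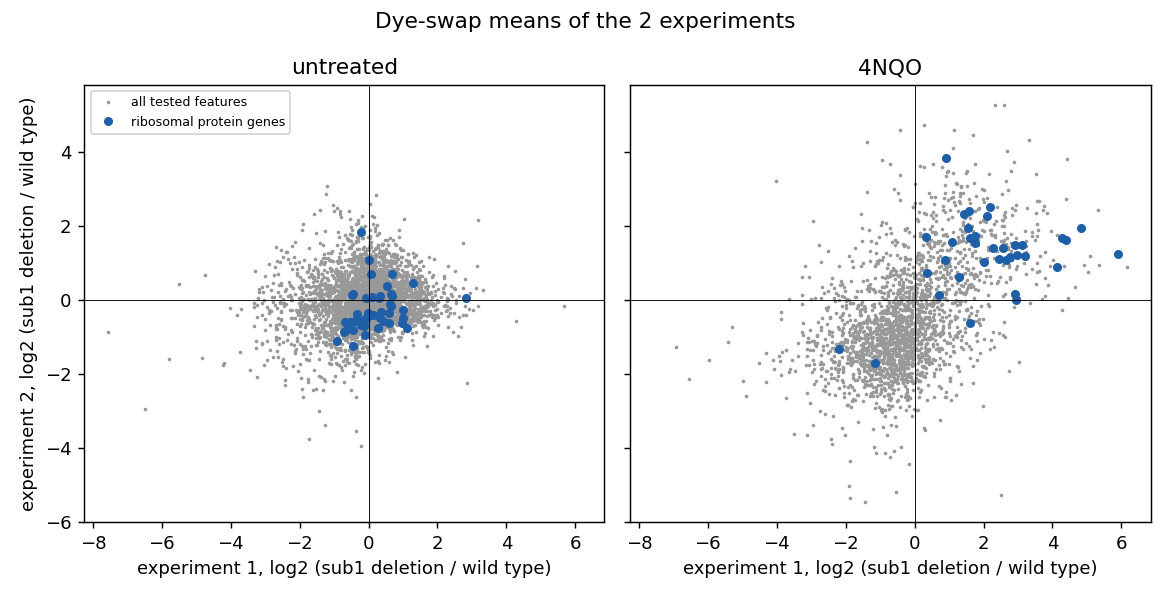
Dye-swap mean log2 ratio (sub1Δ over wild type) in experiment 1 (horizontal) against experiment 2 (vertical), untreated on the left and 4NQO on the right; grey points are tested features and blue points ribosomal protein genes. Of the ribosomal protein genes 33 of 35 have a fitted ratio above 0 with 4NQO, against 20 of 47 untreated. The 2 counts are of unlike gene sets, as fewer genes had the values needed with 4NQO. The median of all tested features was -0.56 with 4NQO and 0.02 untreated.

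The third comparison asked whether the strain difference itself differed between 4NQO and untreated cells. The 2 conditions were sampled 1 h apart, so a difference between them can come from 4NQO or from the added hour. As a list, ribosomal protein genes were shifted upward relative to other features, with a median difference of 2.11 on the log2 scale over 35 genes, none of which passed alone (camera adjusted p = 7.0e-15; 0.59 with an estimated correlation). The list test also called proteasome genes, with a median of 1.88 over 13 genes (adjusted p = 3.3e-06; 0.59 with an estimated correlation), ergosterol synthesis genes, with 1.97 over 5 genes (5.7e-04; 0.59), and glycolysis genes, with 1.42 over 10 genes (0.0071; 0.72). No member of these lists passed over all genes, and fry, which tests against 0, called none of the 4 lists (adjusted p = 0.27, and 0.45 for glycolysis). The ergosterol test for the difference used only 5 of the 8 members tested with 4NQO, all 5 above 0. HES1, called lower with 4NQO, was not among them, so this value is not comparable with that for 4NQO. The oxidative stress list, with a median of 1.78 over 5 genes, did not pass (adjusted p = 0.050).

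No single feature passed in this comparison: of 1654 tested with limma, 0 were called, the smallest adjusted p was 0.19, and 226 had an unadjusted p under 0.05 against 82.7 expected. That number was 156 with the experiment number as a block. It was 73 with arrays scaled to a common median absolute value, so the excess depends on the scaling. The genes with the smallest p for a higher ratio with 4NQO were URA5 (difference 3.68, SE 0.83), YPL216W (3.57, SE 0.81), SNU13, which encodes a shared snoRNP and spliceosome protein (3.19, SE 0.79), RPL28 (3.54, SE 0.92) and YRF1-2, one of a family of near-identical subtelomeric helicase genes (2.99, SE 0.79). Those for a lower ratio were CKS1 (-2.73, SE 0.86), RPL7B (-2.45, SE 0.80), BNA4 (-2.38, SE 0.80), the osmostress kinase gene HOG1 (-2.49, SE 0.84) and ILS1 (-3.20, SE 1.12). None of these 10 passed. Adjusted over the list alone, 21 ribosomal protein genes were higher and 2 lower, and 4 ergosterol genes were higher. Without 4NQO experiment 1 the test called 40 features and without 4NQO experiment 2 it called 53. The glycolysis list lost its call without untreated experiment 2 (adjusted p = 0.18) and without 4NQO experiment 1 (adjusted p = 0.23), and the ergosterol list without 4NQO experiment 1 (adjusted p = 0.14).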

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

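The tests in this part on dye, spot blocks, coding length, brightness and stress response were chosen only after the results were seen, as were the splits of the dye-swap means, while those on exchanged dyes and on other splits or signs of single arrays were written down before their values were known.

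Some lists were singled out because their strain difference itself differed between 4NQO and untreated cells: ribosomal proteins (camera adjusted p = 7.0e-15), proteasome (3.3e-06), ergosterol synthesis (5.7e-04) and glycolysis and gluconeogenesis (0.0071). With an estimated correlation none of them passed (adjusted p = 0.59, and 0.72 for glycolysis), and fry, which asks whether a list differs from 0 and not from other features, called none (0.27, and 0.45 for glycolysis). The ergosterol test for the difference used 5 of the 8 members tested with 4NQO, without HES1. The 4 dye-swap means can be split in 3 ways, too few for a share under 0.05, and the real split called 4 lists against 3 at the highest of the others. Splits of single arrays ignore that the 2 arrays of a dye swap hold the same RNA and decide nothing: 2 of 35 gave as many lists as the real one (6, highest of the others 6), and for single genes, with 0 called, all 35 must reach that count (highest of the others 1).

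The shift of 5 lists with 4NQO was weighed against technical sources. A dye effect alone would put a list on opposite sides of 0 in the 2 dye orientations. That was not seen: all 20 medians (5 lists on 4 arrays, each minus its array's median) lay above 0, whichever dye the mutant carried. The lists were picked for their shift on these same arrays, so the count is no independent support. It does not exclude that a dye effect adds to the shift. The size of the shift did depend on the dye, being larger with the mutant in Cy3 in 10 of 10 pairs of a list and an experiment, for instance 3.06 against 0.57 for oxidative stress in experiment 2, and the cause of this was not tested. Uneven hybridisation across the slide is argued against for the ribosomal protein, proteasome and glycolysis lists, which kept at least 85.1% of their shift after every spot block was centred, and stays open for the oxidative stress list, which kept 71.4%, and for the ergosterol list, which kept 86.7%, because both calls ended (adjusted p = 0.070). Other genes of matched coding length did not share the shift: lists of them had a typical median of -0.46 (highest 0.17), against 1.78 for the members. That 0% of 10000 such lists reached 1.78 is no independent support. The members' lists were picked for their shift in these data, and the matched genes were drawn 1 by 1. A shift that grows with spot brightness may contribute and cannot be told apart from a change in these transcripts, because no intensities were used here and its predictions came out apart: log2 ratios with 4NQO rose with the number of untreated arrays giving a value (Spearman rho = 0.24 across features), from a median of -1.51 with 0 arrays to -0.40 with 4, but 0% of lists drawn from genes with a value on all 4 untreated arrays reached the members' median, where at least 5% had been predicted. That number cannot grade bright spots, because 1654 of the 2194 tested features share its top value of 4. The 0% therefore does not count against a brightness effect. A weaker general stress response in sub1Δ was taken to predict that ribosome biogenesis genes shift as far as ribosomal protein genes. That equal shift was not seen, as ribosomal protein genes exceeded ribosome biogenesis genes by 2.10 in median log2 ratio. The permutation p of 1e-05, the smallest that 100000 permutations can give, is no independent support. Genes are not independent, and the ribosomal protein list was picked for its shift in these data. Trehalose and glycogen genes, with a median of -1.80 over 4 genes, go with a weaker response, but 0 were called lower after centring of array medians. Other stress lists do not share this. General stress genes were at -0.07 over 8 genes and heat shock genes at -0.58 over 9, against -0.56 for all tested features. Oxidative stress genes were at 1.62 over 6 genes. No array measured the response of either strain to 4NQO, so a weaker general stress response stays open. Another difference between the strains in the 4NQO response remains untested.

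Arrays with the same dye orientation resembled each other more than dye-swapped arrays did. The mean correlation of the 12 same-orientation pairs exceeded that of the 16 opposite pairs by 0.22 (0.30 against 0.08). A dye effect of single genes would give this, but the value restates the observation that prompted it and so leaves the cause open. Exchanged dyes on 1 array of untreated experiment 2 could also lower agreement there and cannot be told apart from noise: its arrays correlated at 0.016 and 0.20 with the mean strain ratio of the other 3 experiments, neither clearly negative.

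Changing the signs of the 4 arrays with 4NQO in all 8 possible ways gave 428 called features for the labelled signs and at most 12 for any other assignment. Only 1 of 8 assignments reached the real count, but 8 are too few for a share under 0.05. Most other assignments also set an array against its dye-swap partner, although both hold the same RNA and are averaged. Any signal or offset shared by the arrays then cancels, and their turned medians were all negative (-0.66 to -0.14). The fall from 428 to at most 12 therefore decides nothing about the calls.

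Single arrays stood apart from the other 3 of their condition in 8 of 67 sets of 4 values examined. With 4 independent normal values per set about 3.35 would be expected, but the 2 arrays of a dye swap share RNA. Most sets were also genes picked for their values, and the 3 TDH genes may not be separate. The 3.35 is therefore no chance rate for these sets. All 8 outlying values lay on dye-swapped arrays. The measure is the gap to the nearest array over the whole range. GRE1 in untreated cells had a log2 ratio of 3.34 on the dye-swapped array of experiment 2 against 0.96 to 1.12 (gap share 0.932). With 4NQO, URA5 had 5.48 on the dye-swapped array of experiment 2 against 3.20 to 3.45 (0.887), and ILS1 had -10.2 there against -0.79 to -0.24 (0.944). HES1 had -10.7 on the dye-swapped array of experiment 1 against -1.22 to -0.18 (0.901). On that array RPS22A had 6.72 against 1.23 to 2.11 (0.840), TDH1 5.35 against 1.51 to 1.96 (0.881), TDH2 5.45 against 1.01 to 1.65 (0.858) and TDH3 5.47 against 0.48 to 1.02 (0.892).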

How the results depend on the processing

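Most signs held and many calls did not. Genes changed with 4NQO (428) numbered 269 with all 8 arrays as independent replicates, 249 with the experiment as random block, 212 with array medians centred, 94 with the condition fitted alone and 674 at an adjusted p under 0.10. They numbered 0 with arrays scaled to a common median absolute value, with only genes on all 8 arrays (fewer genes tested), with a dye-swap mean also from 1 array, with dye-swapped arrays taken as already turned, and without the array with most missing values, and 94 to 338 with 1 experiment left out, a lone experiment being assumed to vary like the others. Genes changed untreated (1) numbered 0 with 8 independent arrays, random block, dye term, centring, scaling, genes on all 8 arrays, means also from 1 array, robust variance and without the sparsest array, 3 with spot blocks centred, 8 with every spot separate, 9 with the dye-swapped array of untreated experiment 2 alone taken as already turned, 42 with the condition fitted alone, and 0 to 42 with 1 experiment left out. Genes whose difference changed (0) numbered 2 with spot blocks centred, 13 with the swap of untreated experiment 2 alone taken as already turned, and 0 to 53 with 1 experiment left out. Lists shifted with 4NQO (5) numbered 8 with means also from 1 array, 3 with spot blocks centred, 0 with an estimated correlation, 0 with fry, and 3 to 6 with 1 experiment left out. Lists untreated (0) numbered 1 with 8 independent arrays, random block, dye term, scaling or the swap of untreated experiment 2 alone turned, 2 with centring or without the sparsest array, and 0 to 2 with 1 experiment left out. Lists for the difference (4) numbered 0 with swaps already turned, with an estimated correlation and with fry, and 2 to 5 with 1 experiment left out. With scaling, 3 lists passed for the difference. Without the sparsest array 4 lists passed, 3 higher and 1 lower, and 3 of the main calls were kept. With the experiment number as a replicate block, 0 genes and 4 lists passed for the difference, and it changed no call. A lone experiment gives no spread of its own, so leaving 1 out amounts to fitting the other condition alone. This is why 42 features untreated and 94 with 4NQO recur in these settings. The cause of the other moves was not tested. If all swaps had been turned before deposit, 74 of 88 values would reverse, and which do depends on the relative size of the swapped and unswapped values: untreated ANB1 -0.48, GRE1 -0.53, BGL2 -0.43, SSC1 -0.92, YHR022C 0.25, YGL260W 0.58, ADE2 -0.10, LYS2 0.40; with 4NQO URA5 -0.63, RPL10 -1.05, RPL28 -2.18, CYB5 -0.76, BGL2 -0.49, GPT2 -0.70, YLR257W -0.79, YPL216W -0.82, PRE5 -1.57, RPS25B -1.34, HES1 2.58, CKS1 1.12, DAM1 0.84, ILS1 2.35, GIP1 0.30, PEP1 0.56, GPD1 -0.34, ADE2 0.62, MXR1 -0.94, TRX2 -0.28, SOD1 -0.44, RPS22A -1.44, TDH1 -1.01, TDH2 -0.95, TDH3 -1.19, ADH1 -1.003, ERG25 -0.92, ERG28 -0.51, ERG3 -1.18, SCL1 -1.11, RPN6 -1.38, RPN5 -0.45; for the difference URA5 -0.48, YPL216W -0.78, SNU13 -0.18, RPL28 -2.08, YRF1-2 -1.14, CKS1 1.68, RPL7B 2.11, HOG1 1.28, ILS1 2.9999, GPD1 -0.32, ADE2 0.72, RPS22A -1.34, RPS25B -1.51, TDH2 -1.05, ADH1 -1.03, GPM1 -0.85, TDH1 -0.98, ERG28 -0.30, ERG2 -0.68, ERG25 -1.15, ERG3 -1.10, RPN10 -1.57, PRE7 -0.65, SCL1 -0.87, RPN5 -0.24. Then list adjusted p with 4NQO oxidative stress defence 0.28, ribosomal proteins 0.0069, glycolysis and gluconeogenesis 0.022, ergosterol synthesis 0.14, proteasome 0.015, list adjusted p for the difference ribosomal proteins 0.063, glycolysis and gluconeogenesis 0.063, ergosterol synthesis 0.11, proteasome 0.063, all in the other direction. With the dye-swapped array of untreated experiment 2 alone taken as already turned, signs untreated turned for GRE1 -0.054, ADE2 -0.42, for the difference ADE2 0.17. Without untreated replicate 2, signs untreated turned for ADE2 -0.51, for the difference ADE2 0.25. With arrays scaled to a common median absolute value, signs with 4NQO turned for GPD1 -0.054. Without 4NQO replicate 2, signs with 4NQO turned for GPD1 -1.27, ADE2 0.81, for the difference GPD1 -0.75, ADE2 0.07. Without the array with most missing values, signs with 4NQO turned for GPD1 -0.34, ADE2 0.030. With array medians centred, signs with 4NQO turned for ADE2 0.20. With spot blocks centred, signs with 4NQO turned for ADE2 0.17. Without 4NQO replicate 1, signs for the difference turned for LYS2 0.018. With 1 experiment left out the values ranged for GPD1 with 4NQO -1.27 to 1.59, GPD1 for the difference -0.75 to 2.10, ADE2 untreated -0.51 to 1.99, ADE2 with 4NQO -1.32 to 0.81, ADE2 for the difference -2.24 to 0.25, LYS2 for the difference -1.49 to 0.02. The cause was not tested. Of the 88 named values, centring kept 80 on their side of the threshold with the same sign, robust variance 86, spot blocks 82 and scaling 52. SUB1 gave no value under any setting. Signal over background was not used here, so what faint spots limit was not measured.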

Other observations

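A few genes outside the 5 shifted lists are given here as single values, named after these were seen and with no test of a shared theme. The cytosolic chaperone genes SSA2 and SSB2 were at log2 ratios of 2.55 ± 1.77 and 2.55 ± 2.06 (SD, n = 2) and the alpha-factor gene MF(ALPHA)2 at 2.49 ± 0.75, all past the threshold and all kept after centring of array medians. Genes at the other end included the trehalase gene NTH2 at -2.29 ± 0.95, the iron-retaining cell wall gene FIT2 at -2.59 ± 1.36, above 0 on 1 array, and the meiotic kinase gene IME2 at -1.85 ± 1.07, and these 3 did not pass after centring (adjusted p = 0.078, 0.079 and 0.16). The lowest value of a named gene past the threshold, YMR084W at -4.34 ± 3.12, came from a gene that did not have the same sign on all 4 arrays.

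Of the 199 features called higher with 4NQO, 107 had a single gene name and could thus belong to a list. Of these 107, 42 belonged to the 5 shifted lists, which held 73 of the 1242 named features tested and were picked for their shift. No single gene name was given here for 209 of all 428 called features.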
